A study of Microhyla fissipes with 12 samples.

How the data were processed

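Dorsal muscle RNA of Microhyla fissipes was sequenced at 4 developmental stages, with 3 libraries per stage. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was taken with poly-T beads and fragmented, and cDNA made with random hexamers was sequenced as paired ends on an Illumina HiSeq instrument. Tadpoles were fed spirulina powder, per the labels' protocols. Stage and replicate number were taken from the sample titles. The series calls the libraries biological replicates and does not say how many animals each holds.

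The authors deposited a single file with a column for each library, whose values are FPKM rounded to 2 decimals, and the unit is named by the labels and fits the column sums, which differ between libraries. The assembler, aligner, counting tool and filters are not given in the sources used here. Row names are unigene IDs of the form cluster and number. The companion sequence file that the labels name was not used here, and the table does not pair IDs with gene names. The gene lists fixed before the data were examined (fibre types, thyroid hormone response, proteolysis and markers of other cells among them) were therefore not run. All columns of the table were used.

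An FPKM is a share of the library, so a lower share of the most abundant transcripts raises all other values. An exact 0 can also be a failed estimate in an assembly where 1 cluster holds 224984 unigenes, so a printed group with a library at 0 is given per library, without a fold change. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low unigenes; ratios of mean FPKM are given where named as fold. Counts of reads are unknown, and whole reads could not be recovered from the values, so no count model was used. Relative depth was estimated from the low FPKM values of library pairs, which cluster at ratios of small whole numbers. The precision that depth gives cannot be stated beyond that.

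Unigenes with an FPKM of at least 1 in at least 3 of 12 libraries were tested, 123813 in all. limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8) was fitted to log2(FPKM + 1) with stage as the only term and moderated variances with a mean-expression trend. All stages entered 1 fit because 3 libraries estimate the spread poorly. A unigene differed among stages at a Benjamini-Hochberg adjusted p under 0.05 by the moderated F test. In each of 5 contrasts it was called at an adjusted p under 0.05 and a log2 difference of at least 1 in size. Adjustment was within each contrast. The p-values measure the spread between these libraries, which may be technical in part.

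The design fixed before the data were examined used all 12 libraries as separate samples. Replicates were compared first, and S45 replicates 2 and 3 differed by about as much as sampling noise, so their mean was used as 1 sample and the fit held 11 samples. This departs from the fixed design, and the number called in each contrast with 12 separate libraries is printed as well. The comparison used the robust SD of the log2 ratio of each of the 66 pairs of libraries in 5 classes of mean FPKM, and the noise expected in the highest class was scaled from the lowest by the square root of FPKM.

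Replicate similarity was the mean Pearson correlation within stages minus that between stages, with a 1-sided exact permutation test over all assignments. The share of total FPKM in the 100 highest unigenes was compared with 2-sided exact permutation tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Unigenes named in the text followed a rule fixed before the data were examined. Per contrast it took at most 2 called higher and 2 called lower with the largest log2 difference, among those with a mean FPKM of at least 10 in the higher stage and no overlap between the libraries of the stages. Unigenes given by abundance rank, and counts by class of abundance, were chosen after seeing the data.

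The limma step was tested on simulated data in which 200 of 123813 unigenes were changed. For S43 against S40, 18% of those changed by 2 and 68% of those changed by 4 on the log2 scale were recovered, with 4 false calls. For S45 against S36 these were 7% and 56%, with 7 false calls. The simulated noise was independent between unigenes and libraries, and the changed unigenes were drawn from the more abundant ones. The likeness of some real libraries across stages was not simulated. These false calls therefore do not tell how many to expect in the real data.

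Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a mean FPKM of at least 5, median-ratio scaling and quantile normalization, robust eBayes and eBayes without trend, a fit of the stages in the contrast alone, no fold threshold, the replicate number as a block, each library left out in turn, Spearman correlation and the 10 or 1000 highest unigenes. The replicate block was run in the fit of 12 separate libraries, as fixed. Added after seeing the data were the counting of S45 replicates 2 and 3 as 1 sample, the permutation test over 4 stages, the correlations by stage and the removal of 3 pairs of libraries that stood out: S36 replicate 3 with S40 replicate 1, S36 replicate 1 with S43 replicate 2, and S43 replicate 3 with S45 replicate 1.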

Results

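Messenger RNA of dorsal muscle was profiled in the frog Microhyla fissipes at 4 developmental stages of metamorphosis, named S36, S40, S43 and S45 after stages 36, 40, 43 and 45. Each stage had 3 libraries, 12 in all, which the series describes as biological replicates. The question the design poses is how the transcripts of dorsal muscle differ among these stages, between consecutive stages and between the first and the last. The deposited table lists FPKM (mapped fragments scaled for unigene length and library size) for 468578 unigenes, the transcripts of a gene catalogue assembled from reads, of which 44784 were listed at 0 in every library. The table does not pair unigene IDs with gene names, so genes and pathways are not named here. A total of 123813 unigenes entered the tests.

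Total FPKM per library ranged from 1219979 in S36 replicate 2 to 1688307 in S43 replicate 3. Read counts are not part of the table, so the absolute depth is unknown. Relative depth, read from the steps between low FPKM values and set to 1.0 for S45 replicate 1, was 1.2, 1.46 and 1.31 in S36 replicates 1, 2 and 3 and 1.38, 1.27 and 1.29 in those of S40. It was 1.33, 2.19 and 2.45 in S43 and 1.93 and 2.0 in S45 replicates 2 and 3. Of 55 cross-checks of these depths between other pairs of libraries, 48 closed within 0.15 on the log2 scale and 7 were off by a factor of 2. These cross-checks leave out S45 replicate 1, so its depth relative to all others may be off by that factor.

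Between 68062 and 140066 unigenes per library reached an FPKM of 1, the fewest in S43 replicate 1 and the most in S45 replicate 1. One cluster of the assembly, Cluster-199519, held 224984 of the unigenes, while the next largest of the 221242 clusters held 15. Outside that cluster, S43 replicate 3 had 56543 unigenes at an FPKM of 1 or more and S45 replicate 1 had 49802, against 8388 to 24966 in the other 10 libraries.

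Pooled over all stages, libraries of one stage were more alike than libraries of different stages, but not at each stage. The mean Pearson correlation of log2(FPKM + 1) across unigenes was 0.729 within stages and 0.675 between them, a difference of 0.054 (1-sided exact permutation p = 0.0083, 92400 assignments). By stage, a summary chosen after seeing the data, the mean correlation within S43 was 0.639, about that of S43 with S36 (0.636), S40 (0.645) and S45 (0.648). Within S36 it was 0.763 against 0.769 between S36 and S40, which also lay above the pooled mean within stages. Within S40 it was 0.784 and within S45 0.729, the latter from 1 pair of samples. The highest correlation of S43 replicate 2 was with S36 replicate 1 (0.742) and that of S43 replicate 3 with S45 replicate 1 (0.726). The first principal component held 27.6% of the variance and the second 16.8%. Without both S36 replicate 3 and S40 replicate 1 the difference was 0.033 (1-sided exact permutation p = 0.13).

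S45 replicates 2 and 3 differed by about as much as sampling noise and were counted as 1 sample, so that S45 has n = 2. The SD of their log2 ratio was 0.266 for unigenes at a mean FPKM of 10 to 30 and fell to 0.028 at 1000 or more, where noise that scales with the number of fragments would give 0.025. The other 65 pairs included 1 more close pair, S36 replicate 3 and S40 replicate 1, which come from different stages. Its SD at a mean FPKM of 1000 or more was 0.065 against a noise level of 0.025, and those of the remaining 64 pairs were 0.166 to 1.09. Both libraries were kept, and counts without them are given below.

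**Figure D1:**
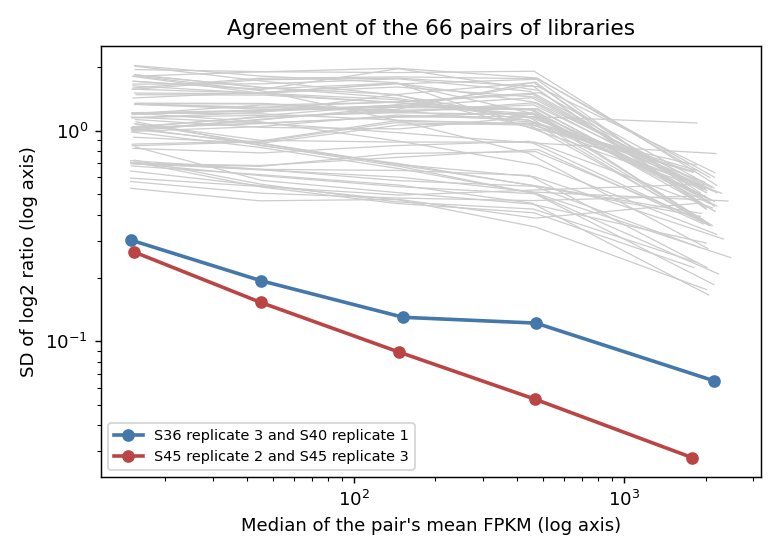
Agreement of the 66 pairs of libraries. Each line is 1 pair, with the median of the pair's mean FPKM in 5 abundance classes on the x axis (log axis) and the robust SD of the log2 ratio of the libraries on the y axis (log axis); S45 replicates 2 and 3 (red) reach 0.028 in the highest class, S36 replicate 3 and S40 replicate 1 (blue) 0.065, and the other pairs (grey) stay at 0.166 or above.

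The most abundant transcripts took a smaller share of the total in late libraries. The 100 highest unigenes of each library held 43.0% ± 3.18 of total FPKM at S36 (SD, n = 3), 39.7% ± 6.14 at S40 (n = 3), 31.4% ± 5.55 at S43 (n = 3) and 23.1% ± 1.67 at S45 (n = 2). A permutation test over all 4 stages at once, chosen after seeing the data, gave an exact p of 0.015 over 92400 assignments, against an exact p of 0.052 for the 10 highest and 0.029 for the 1000 highest. Single steps were not resolved with so few samples. The difference was -3.33 percentage points from S36 to S40 (exact 2-sided permutation p = 0.4), -8.35 from S40 to S43 (exact permutation p = 0.2) and -8.22 from S43 to S45 (exact permutation p = 0.2). From S36 to S40 it was -1.5 without S36 replicate 2, -0.2 without S40 replicate 2 and -6.34 without S40 replicate 3. From S40 to S43 it was -5.34 without S40 replicate 3, and from S43 to S45 -5.27 without S43 replicate 1. From S36 to S45 it was -19.9 percentage points (exact permutation p = 0.1, the smallest that 3 against 2 samples can give), and every S45 library lay below every S36 library.

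**Figure D2:**
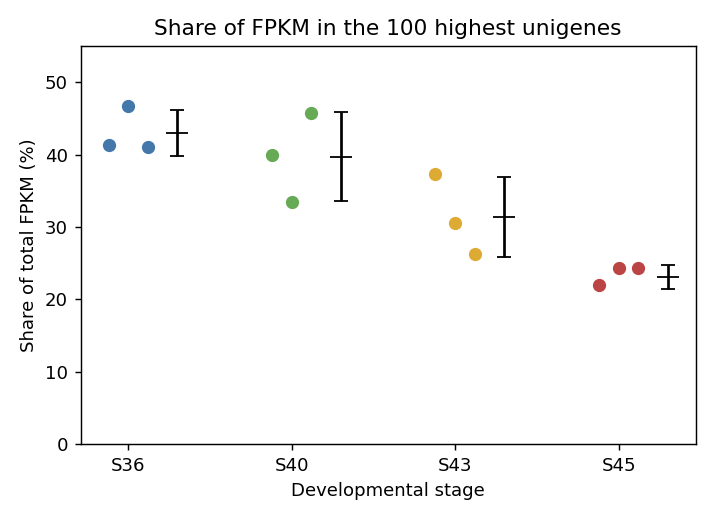
Share of total FPKM (%) in the 100 highest unigenes of each library, by developmental stage. Points are the 12 libraries, bars are mean ± SD with S45 replicates 2 and 3 counted once; the mean goes from 43.0% at S36 to 23.1% at S45.

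Over all 4 stages, 1214 of the 123813 unigenes differed among stages by limma's moderated F test with Benjamini-Hochberg adjustment. Their mean was highest at S36 for 177, at S40 for 179, at S43 for 277 and at S45 for 581. The 581 are 47.9% of the 1214, against 52.6% among unigenes that did not pass. The leading stage changed with scaling: for S36, S40, S43 and S45 the numbers were 217, 99, 299 and 227 with median-ratio scaling and 329, 185, 223 and 285 with quantile normalization. With S45 replicates 2 and 3 entered as separate samples, limma called 5216, with the mean highest at S36 for 500, S40 for 607, S43 for 834 and S45 for 3275. Without 1 library the count was 319, 321 and 550 (S36 replicates 1, 2 and 3), 396, 445 and 398 (S40), 1374, 861 and 4913 (S43) and 390, 1178 and 1155 (S45).

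The 10 unigenes with the highest mean FPKM all had lower values at S45 than at S36, and 4 of them fell by the limma test. The ranks came from the mean over these same samples, with fewer from S45, which favours unigenes that were high at early stages. The unigene of abundance rank 5 had an FPKM of 40400 ± 13900 at S36 (SD, n = 3), 34610 ± 20500 at S40 (n = 3), 4592 ± 2250 at S43 (n = 3) and 1739 ± 221 at S45 (n = 2). Its mean FPKM was 23.2-fold lower at S45 than at S36 (log2 difference -4.49 ± 0.52 SE, limma adjusted p = 0.0054). Rank 8 went from 18010 ± 5760 to 1539 ± 583, 11.7-fold lower (log2 -3.55 ± 0.43, limma adjusted p = 0.0071), and rank 10 from 14370 ± 4840 to 945.4 ± 100, 15.2-fold lower (log2 -3.88 ± 0.63, limma adjusted p = 0.025). Rank 7 went from 16020 ± 2750 to 6404 ± 1560, 2.5-fold lower (log2 -1.33 ± 0.23, limma adjusted p = 0.029). Ranks 5 and 8 were already lower at S43 than at S40 (log2 -2.89 and -2.94, limma adjusted p = 0.036 and 0.018), but this passed in 9 and 20 of 26 alternatives. The highest unigene of all had 36270 ± 6590 at S36 and 19440 ± 3280 at S45, which did not pass (limma adjusted p = 0.1). Rank 20 had the opposite course, with 689.9 ± 871 at S36 and 7650 ± 2620 at S45, and did not pass either (limma adjusted p = 0.075). Of 26 alternatives, the highest unigene passed in 2 and rank 20 in 5.

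**Figure D3:**
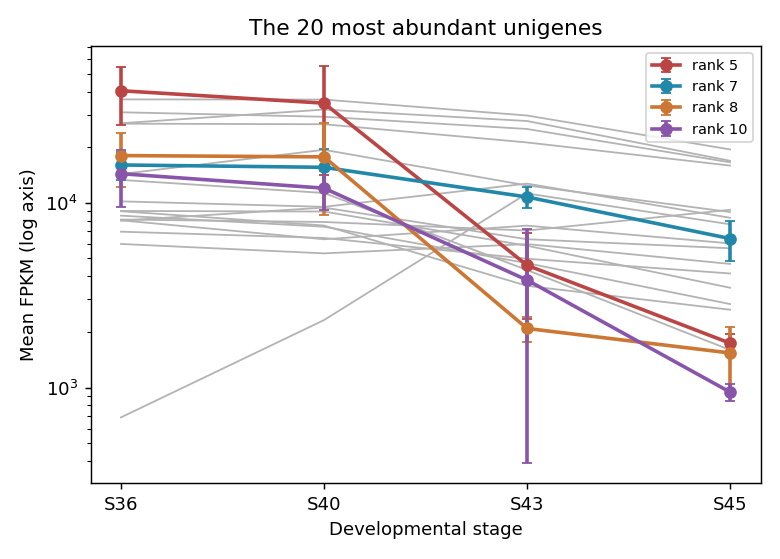
Mean FPKM (log axis) of the 20 most abundant unigenes at each developmental stage. The 4 of the 10 highest that were called lower at S45 than at S36 are drawn in colour with SD bars (n = 3, and n = 2 at S45) and the others in grey; rank 5 goes from 40400 at S36 to 1739 at S45.

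Abundance classes were chosen after seeing the data and rest on the same mean over all samples. Among the 100 most abundant unigenes, 13 were called lower and 1 higher at S45 than at S36, and 86 were not called. With median-ratio scaling 35 were lower and 0 higher, with quantile normalization 8 and 2, with S45 replicates 2 and 3 separate 15 and 3, and in a fit of S36 and S45 alone none. With eBayes without trend 4 were lower and 0 higher, and with a pseudocount of 0.1 these were 6 and 0. Without both S36 replicate 3 and S40 replicate 1 they were 4 and 3, and without both S36 replicate 1 and S43 replicate 2 they were 1 and 0. Median-ratio scaling divided the S45 samples by 1.414 and 1.431 and the S36 samples by 0.863 to 1.022. It moved every S45 value down relative to S36, which favours lower calls such as the 35. The 10 highest, lower before it, therefore had to stay lower. Under quantile normalization 5 of the 10 were lower. The number lower was 3, 3 and 4 without S36 replicates 1, 2 and 3, 7 without S40 replicate 1 and 0 without S45 replicate 1, and 10 to 14 without any other library. Without S36 replicate 3, 5 were higher against the 4 lower, so the balance turned. In a fit of S36 and S45 alone the limma adjusted p of ranks 5, 8 and 10 was 0.067. Over 26 alternatives the adjusted p ran from 0.00092 to 0.067 for rank 5, from 0.0019 to 0.098 for rank 8, from 0.0042 to 0.19 for rank 10 and from 0.0063 to 0.12 for rank 7.

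From S36 to S40 only 2 unigenes were called, both higher at S40. Cluster-199519.93307 was listed at 0 in all 3 S36 libraries and at 52.1, 22.25 and 44.22 FPKM in the S40 libraries (limma adjusted p = 0.006). Cluster-199519.39205 was listed at 0 in every library but those of S40, where it had 10.28, 10.13 and 10.11 FPKM (limma adjusted p = 0.016). The former passed in 19 of 26 alternatives and the latter in 15 of 25. At an unadjusted limma p under 0.05 there were 3882 unigenes. With no difference between stages, a share of 0.05 of the 123813 tested would fall there, which is more than the 3882. With S45 replicates 2 and 3 separate 3 were called. The count was 0, 0 and 12 without S36 replicates 1, 2 and 3, 7, 1 and 0 without those of S40, 3, 3 and 4 without those of S43 and 1, 3 and 2 without those of S45. It was 0 without both S36 replicate 3 and S40 replicate 1.

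From S40 to S43, 172 unigenes were called higher and 223 lower, 395 in all, a balance that turned without S43 replicate 1 (393 higher and 326 lower) and without S43 replicate 2 (143 and 71). Cluster-199519.37043 rose from 0.953 ± 0.38 to 662 ± 782 FPKM (SD, n = 3 each; log2 difference 7.33 ± 1.1 SE, limma adjusted p = 0.03), with S43 libraries at 1541.7, 397.67 and 47.3. Cluster-199519.65947 rose from 2.03 ± 1.71 to 241 ± 186 (log2 5.98 ± 0.73, limma adjusted p = 0.014) and stood at 26.1 ± 7.26 at S45 (n = 2). Cluster-199519.115432 fell from 276.63, 269.15 and 237.38 in the S40 libraries to a listed 0 in all 3 S43 libraries (limma adjusted p = 0.038); at S45 it had 171.93 in replicate 1 and 0 in replicates 2 and 3. Cluster-199519.164678 fell too (limma adjusted p = 0.047), from 7194.62, 565.83 and 20.09 in the S40 libraries to 0.43 in S43 replicate 2 and a listed 0 in S43 replicates 1 and 3. Its first value belongs to a block of 25 unigenes found at 100 FPKM or more and 8-fold over every other library in S40 replicate 1, which made up 2.39% of that library. In the order given, these 4 passed in 14, 21, 13 and 10 of 26 alternatives. Among the 100 most abundant unigenes 4 were lower and 0 higher. The 4 became 1 with median-ratio scaling, 5 with quantile normalization, 5 with S45 replicates 2 and 3 separate and 0 in a fit of S40 and S43 alone. They became 1, 2 and 1 without S36 replicates 1, 2 and 3, 0, 2 and 0 without those of S40, 6, 1 and 1 without those of S43 and 1, 3 and 4 without those of S45.

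With median-ratio scaling the S40 to S43 split was 300 higher and 208 lower, with quantile normalization 218 and 313, and with S45 replicates 2 and 3 separate 327 and 560. The count was 136, 142 and 173 without S36 replicates 1, 2 and 3, 46, 54 and 43 without those of S40, 719, 214 and 688 without those of S43 and 351, 340 and 357 without those of S45, and a fit of S40 and S43 alone called 5. It was 13 without both S36 replicate 3 and S40 replicate 1, 58 without both S36 replicate 1 and S43 replicate 2, and 1284 without both S43 replicate 3 and S45 replicate 1.

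From S43 to S45, 1095 unigenes were called higher and 54 lower, 1149 in all. Of the 1095, 975 had a mean FPKM under 10, a share like that of all tested unigenes (110182 of 123813). Among the 100 most abundant unigenes none was called. Without S43 replicate 3, 4 of the 100 were called lower and 1 higher, with S45 replicates 2 and 3 separate 2 and 1, with the replicate block in that fit 1 and 1, and with no filter 0 and 1. Cluster-199519.146269 was listed at 0 in S43 replicates 1 and 2 and at 9.98 FPKM in replicate 3, and had 91.6, 108.73 and 100.79 in the S45 libraries (limma adjusted p = 0.03), after 9.01, 22.09 and 7.22 in those of S40. Cluster-199519.48086 was listed at 0 in all 3 S43 libraries and had 46.95, 45.24 and 31.99 in those of S45 (limma adjusted p = 0.038). Cluster-199519.37063 fell from 32.68, 26.71 and 6.23 to a listed 0 in every S45 library (limma adjusted p = 0.026). Cluster-199519.163866 fell from 40.38, 9.44 and 45.99 in the S43 libraries to 2.84 in S45 replicate 1 and a listed 0 in S45 replicates 2 and 3 (limma adjusted p = 0.039). In the order given, these 4 passed in 12, 10, 18 and 10 of 26 alternatives. The median log2 difference of all tested unigenes was 0.38, so most unigenes had slightly higher FPKM values at S45. The median was 0.051 with median-ratio scaling and -0.048 with quantile normalization. Both methods bring the libraries to a common level, so a median near 0 was given by them and does not test this shift.

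With median-ratio scaling the S43 to S45 split was 100 higher and 18 lower, with quantile normalization 86 and 12, and with S45 replicates 2 and 3 separate 5545 and 289. The count was 252, 444 and 293 without S36 replicates 1, 2 and 3, 276, 735 and 287 without those of S40, 152, 149 and 7888 without those of S43 and 144, 1164 and 1203 without those of S45, and a fit of S43 and S45 alone called 0 (19148 at an unadjusted limma p under 0.05 in the fit of all stages). It was 40 without both S36 replicate 3 and S40 replicate 1, 26 without both S36 replicate 1 and S43 replicate 2, and 4004 without both S43 replicate 3 and S45 replicate 1.

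Between the first and the last stage, 703 unigenes were higher at S45 and 175 lower, 878 in all. Cluster-199519.148711 was listed at 0 in all S36 libraries, had 13.26, 64.77 and 38.91 FPKM at S40 and 333.68, 152.15 and 181.76 at S45 (limma adjusted p = 0.002). Cluster-199519.75953 rose from 8.54 ± 8.31 at S36 (SD, n = 3) to 1290 ± 811 at S45 (n = 2; log2 difference 7.26 ± 0.92 SE, limma adjusted p = 0.0084), with 2490 ± 2640 at S43. Cluster-199519.119935 fell from 1110 ± 621 to 5.82 ± 0.17 (log2 -7.18 ± 0.76, limma adjusted p = 0.0039) and was at 10.3 ± 11.8 at S43. Cluster-199519.113541 had 46.91, 131.8 and 292.14 in the S36 libraries and was listed at 0 in every S43 and S45 library (limma adjusted p = 0.002). In the order given, these 4 passed in 25, 23, 25 and 25 of 26 alternatives. By mean FPKM there were 562 higher and 93 lower under 10, 109 and 36 from 10 to 100, 28 and 28 from 100 to 1000, and 4 and 18 at 1000 and over. These classes were counted in the fit of 11 samples only, and the excess of lower calls among the 100 most abundant unigenes did not hold in some alternatives: 5 higher and 4 lower without S36 replicate 3, and none without S45 replicate 1 or in a fit of S36 and S45 alone.

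The median log2 difference of all tested unigenes between S36 and S45 was 0.556, and relative to the median unigene the excess of higher calls was smaller. With median-ratio scaling 265 were higher and 222 lower, with quantile normalization 267 and 253, and with S45 replicates 2 and 3 separate 3611 and 648. The count was 125, 132 and 300 without S36 replicates 1, 2 and 3, 450, 574 and 472 without those of S40, 1423, 1127 and 7863 without those of S43 and 177, 1104 and 985 without those of S45, and a fit of S36 and S45 alone called 0 (26678 at an unadjusted limma p under 0.05 in the fit of all stages). It was 151 without both S36 replicate 3 and S40 replicate 1, 88 without both S36 replicate 1 and S43 replicate 2, and 3120 without both S43 replicate 3 and S45 replicate 1.

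Stage S43 was also set against the mean of S40 and S45, to find transcripts that stood apart at that stage. There were 106 unigenes higher and 360 lower at S43, 466 in all. Cluster-199519.65947, which also rose from S40 to S43, was higher (log2 difference 4.34 ± 0.66 SE, limma adjusted p = 0.041). Cluster-199519.163866 was listed at 0 in all S36 and S40 libraries and was higher at S43 (limma adjusted p = 0.031). Cluster-199519.93307 was lower, listed at 0 in all S43 libraries and at 24.92, 16.16 and 14.87 in those of S45 (limma adjusted p = 0.0032). Cluster-199519.92163 was lower, with 0.39 FPKM in S43 replicate 1 and a listed 0 in S43 replicates 2 and 3, against 13.73, 28.04 and 21.7 in the S40 libraries and 38.61, 52.99 and 47.47 in those of S45 (limma adjusted p = 0.0032). In the order given, these 4 passed in 13, 14, 24 and 24 of 26 alternatives.

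With median-ratio scaling the split of this contrast was 73 higher and 38 lower, with quantile normalization 110 and 130, and with S45 replicates 2 and 3 separate 378 and 2556, so the excess of lower values at S43 did not hold under median-ratio scaling. It did not hold without S43 replicate 2 either (22 higher and 11 lower). The count was 4, 10 and 5 without S36 replicates 1, 2 and 3, 8, 9 and 5 without those of S40, 20, 33 and 4063 without those of S43 and 19, 400 and 465 without those of S45. It was 0 without both S36 replicate 3 and S40 replicate 1 and 0 in a fit without S36, with 19373 unigenes at an unadjusted limma p under 0.05 in the fit of all stages. It was 6 without both S36 replicate 1 and S43 replicate 2, and 3729 without both S43 replicate 3 and S45 replicate 1.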

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

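The fit of 11 samples and the removal of pairs of libraries were chosen after seeing the data, while the fit of 12 separate libraries was the fixed design. Counts of called unigenes depended on nearly every setting, and scaling, no filter or the removal of a library changed or turned the balance of higher and lower calls from S40 to S43 and for S43 against the mean of S40 and S45. Some directions held. Replicate similarity stayed above 0. The share of FPKM in the 100 highest unigenes stayed lower at the later stage in every comparison and alternative run. Among the 467 results of the named unigenes under alternatives, 315 stayed on their side of the threshold and 152 no longer passed. None reversed, but the rule that named them asked for large differences without overlap between stages, so a reversal was unlikely from the start. The cause of a changed count was not tested unless the setting itself gives it (fewer samples, fewer unigenes tested, more samples counted). Counts below follow the order S36 to S40, S40 to S43, S43 to S45, S36 to S45 and S43 against the mean of S40 and S45, with those that stayed within 1.5 times left out by name. With a pseudocount of 0.1 the first 4 were 17, 824, 162 and 474, and with 0.5 the first was 4 and S43 to S45 740. Without a filter, S40 to S43 gave 100, S36 to S45 1539 and S43 against the mean 6. With a mean FPKM of at least 5, S43 to S45 gave 165 and S36 to S45 370. Median-ratio scaling gave 118, 487 and 111 for the last 3, and quantile normalization 98, 520 and 240. S43 against the mean gave 247 with robust eBayes and 824 without the trend. Fits of the stages in the contrast alone gave 0, 5, 0, 0 and 0. With S45 replicates 2 and 3 separate the last 4 were 887, 5834, 4259 and 2934. The threshold on the log2 difference removed no call. Without both S36 replicate 3 and S40 replicate 1 the counts were 0, 13, 40, 151 and 0, without both S36 replicate 1 and S43 replicate 2 they were 0, 58, 26, 88 and 6, and without both S43 replicate 3 and S45 replicate 1 they were 0, 1284, 4004, 3120 and 3729.

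Unigenes differing among stages numbered 735 without a filter, 5216 with 12 libraries, and 160, 134 and 4432 without the 3 pairs of libraries in the same order. The stage of highest mean moved with them. Without a filter it was S36 for 94, S40 for 78 and S43 for 108. It was S40 for 104 and S45 for 313 at a mean FPKM of at least 5, S40 for 99 and S45 for 227 with median-ratio scaling, and S36 for 329 and S45 for 285 with quantile normalization. For S36, S40, S43 and S45 it was 500, 607, 834 and 3275 with 12 libraries, 30, 19, 48 and 63 without the first pair, 30, 20, 28 and 56 without the second, and for the last 3 stages 276, 791 and 3179 without the third. Replicate similarity without the first pair was 0.033, and 0.041 to 0.074 with 1 library left out.

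With the replicate number as a block, in the fit of 12 libraries, the counts were 1, 134, 3500, 1517 and 842, 1631 unigenes differed among stages, and S45 was the highest stage for 944. The numbers did not pair the libraries: correlations of same-numbered libraries of different stages ran from -0.228 to 0.119 (median -0.016), 1 of 18 was over 0.1, and 1 library correlated best with one of its own number.

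Leaving out 1 library at a time gave 319 to 4913 unigenes differing among stages, and 0 to 12, 43 to 719, 144 to 7888, 125 to 7863 and 4 to 4063 calls in the 5 contrasts. The stage of highest mean was S36 for 50 to 287, S40 for 44 to 339, S43 for 67 to 604 and S45 for 140 to 3683. A stage left with 1 sample was assumed to vary like the others. The high ends came without S43 replicate 3, except 12 (without S36 replicate 3) and 719 (without S43 replicate 1). The gene lists and their alternatives were not run, since the table holds no gene names. Depth limits these counts in a way that cannot be given, as read counts are unknown.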

Other observations

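All tests in this part were chosen after the results were seen. Unigenes at an FPKM of 100 or more and 8-fold over every other library numbered 25 in S40 replicate 1, 11 in S45 replicate 1, 8 in S43 replicate 1 and 6 in S43 replicate 2, and at most 1 in the others. In S43 replicate 1 they made up 0.65% of total FPKM, with a highest value of 5731.98. In the S40 replicate 1 block of 25 unigenes the summed FPKM was 31589.6, and the next highest library, S40 replicate 2, had 1174.8.

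S36 replicate 3 and S40 replicate 1 were closer than any other pair from different stages. Their SD of the log2 ratio at a mean FPKM of 1000 or more was 0.065. In the 8 other S36 to S40 pairs it was 0.166 to 0.78. The pair was picked as the closest, so its rank was given. Only the size of the gap argues against the nearness of the stages as the cause. A library deposited under both names is argued against too, since noise would give an SD of 0.025 at that abundance, and S45 replicates 2 and 3 reached 0.028. Of 4078 unigenes at an FPKM of 30 or more, 378 were over 2-fold apart. That count was not made for other pairs, and a listed 0 can be a failed estimate. RNA shared in part is a candidate explanation. Both libraries held the unigenes that mark S36 replicate 1 and S43 replicate 2 at trace level, 0.171% and 0.135% of total FPKM. The highest share in the 8 remaining libraries was 0.03%. As the pair was alike across unigenes in general, other causes of that likeness could give this trace too. It does not single out shared RNA. Shared animals or a shared preparation stay open, since the labels give neither.

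S36 replicate 1 and S43 replicate 2 shared 530 unigenes at an FPKM of at least 3 and 8-fold over all other libraries, 499 of them in the largest cluster, and these held 2.7% and 5.168% of total FPKM. The other libraries of both stages held at most 0.171%, but the set was picked as 8-fold over all other libraries. A low share there was therefore given by the selection and cannot decide on stage as the cause. In 155 of these unigenes the ratio of the libraries was nearly constant, with a median of 2.07. Its robust SD was 0.311 on the log2 scale, against 0.843 in 1878 other unigenes. Those others were not picked as high in both libraries, so the spreads are not like for like. A nearly constant ratio is what RNA from another source in different amounts may give. A sequence variant of the animals cannot be told apart from this without the sequences: 13 unigenes of the other libraries were missing from both, under the 40 of another pair, but a heterozygous variant would leave none missing. Other biological explanations were not tested.

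S43 replicate 3 and S45 replicate 1 held many unigenes outside the largest cluster at low level, 56543 and 49802 at an FPKM of 1 or more, and shared 1032 unigenes found in no other library at a comparable level. Depth is argued against as the whole cause, since all unigenes outside that cluster held 12.71% and 12.3% of total FPKM against at most 6.57% in the other libraries, and depth changes how many unigenes are found but not the share they hold. The other S43 and S45 libraries had at most 24966, but the 2 libraries were picked as the highest. Only the size of the gap therefore argues against stage as the whole cause. Next highest were S45 replicates 3 and 2, with 24966 and 23399 unigenes. Unigenes outside that cluster held 6.57% and 6.19% of their total FPKM, against at most 4.75% in the remaining libraries, so a part of stage S45 stays open. Of the shared unigenes 80.4% lay outside the largest cluster, and 202 of 1032 lay in it. In other pairs with S43 replicate 3 the number in it ran from 23 of 125 (with S40 replicate 1) to 27 of 71 (with S36 replicate 3). The 80.4% is therefore not particular to this pair and does not point to a source common to both. Without sequences, RNA or DNA from another source cannot be told apart from other origins.

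Chance was weighed by other splits of the samples. For unigenes differing among stages, 4 of 100 splits of the 11 samples, the real one included, gave at least the real 1214. This is under a share of 0.05 so narrowly that chance is at most weakly excluded. The highest other split gave 7392, several times the real count. It put S36 replicate 1 with S43 replicate 2, S36 replicates 2 and 3 with S40 replicate 1, and S43 replicate 3 with the S45 samples. S40 replicates 2 and 3 stood with S43 replicate 1. This 1 split kept part of the stage grouping, so it points to likenesses across stages in addition to stage. Between S36 and S40, 7 of 10 splits gave at least the real 2, the highest other 42, and between S40 and S43 only the real split (1 of 10) gave 395, the highest other 23. These 10 splits are too few for a share under 0.05.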
